A study of Gossypium hirsutum with 2 samples.

How the data were processed

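RNA was sequenced from 2 samples of upland cotton (Gossypium hirsutum) at 10 days post anthesis, 1 library per sample. The series title speaks of 2 cotton species, but both samples are labelled Gossypium hirsutum. One was fiber of the wild-type cultivar Xuzhou142 (WT fiber). The other was ovule of XZ142FLM, a line whose seeds are labelled fuzzless and lintless, with the genotype li3li3n2n2 (FL ovule). Per the labels' protocols, total RNA was treated with DNase and divided into an oligo-dT part and a ribosomal-RNA-depleted part before sequencing on an Illumina HiSeq instrument. The oligo-dT part served to measure transcripts of nuclear genes, per the labels. The labels do not say whether the deposited values come from one part or from both.

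Each deposited table has 1 row per sequence named Unigene, a name commonly given to assembled transcript sequences, with its length, its number of unique reads, its RPKM and annotation text. The deposited counts are whole numbers of unique reads per unigene, per the file headers, and they sum exactly to the total printed in each header. The deposited RPKM values (reads per kilobase of unigene, scaled to the library's read total) were made by the authors from those counts. Recomputing count divided by length and by the header total gave the RPKM of every row to within a relative error of 5.1e-15. Bowtie and Bowtie2 are listed in the submitters' processing notes without versions or roles. The assembler, the annotation database, the genome build and the strand setting are not given in the sources used here. No unigene carries a genome position, and 0 of the 136262 unigene identifiers matched the reference gene table, so names below are the annotation texts of the deposited tables and positions are not given. The unigenes have lengths of 201 to 27882 bases. Several unigenes can come from 1 gene or from near-identical homoeologous copies. Reads could be divided among them, so values of single unigenes are uncertain in that respect. Coverage percentages in the deposited tables were not used.

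WT fiber had 45.6 M reads on 127466 unigenes and FL ovule had 53.4 M reads on 133483 unigenes. The 2 tables share 124687 unigenes, all with the same length in both. A unigene missing from a table was taken as 0 reads. The 30 most-read unigenes of each library held 21.1% of its reads in WT fiber and 38.5% in FL ovule. RPKM shares the read total with these sequences, so their abundance lowers the RPKM of every other unigene in that library. One read on a unigene of 1 kb equals 0.0219 RPKM in WT fiber and 0.0187 RPKM in FL ovule. A count of 0 allows up to 3 reads, or 0.0658 and 0.0562 RPKM for 1 kb.

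A unigene was called measured at an RPKM of 1 or more in at least 1 library, which left 63258, of which 41574 had annotation text. The ratio was log2((RPKM in WT fiber + 1) / (RPKM in FL ovule + 1)); the pseudocount of 1 understates the change of low unigenes. With 1 library per group no test of the groups is possible. Counts of unigenes past 2-fold describe these libraries. Intervals of fold differences are exact (Clopper-Pearson) 95% intervals from the read counts and cover counting error only, not variation between plants or library preparations; folds with an interval are ratios of RPKM without the pseudocount. Reads without molecular identifiers are not independent molecules, so these intervals are too narrow even for counting error.

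Before the data were examined, 31 gene lists were fixed as patterns on annotation text, among them markers of embryo and endosperm, seed coat, green tissue, vascular tissue and dividing cells. The median ratio of each list with at least 5 measured members was placed among the medians of 10000 random lists of the same size drawn from measured, annotated unigenes and matched on mean expression in 20 bins. The fixed plan did not say from which unigenes to draw. They were first drawn from all measured unigenes. After that result had been seen, they were drawn from annotated ones, since a unigene without annotation text cannot enter a list, and the first choice is kept as an alternative. A list was called apart below the 2.5th or above the 97.5th percentile. The rule for named unigenes was also fixed then. It takes the 10 annotated unigenes with the largest ratio in each direction at an RPKM of 10 or more, the 2 members of each list with the largest absolute ratio at an RPKM of 5 or more, and the 5 most abundant unigenes of each library. Alternatives changed the pseudocount to 0.1 or 5, the filter on low values, the fold threshold to 4, the scaling (a common RPKM sum of 1000000, the median ratio of unigenes at 5 RPKM or more in both libraries, the upper quartile), the summary from median to mean, and the set of unigenes. Further alternatives were chosen after seeing the data: library totals without the 30 most-read unigenes, 1 unigene per annotation text, thinned reads, the respiratory list without vacuolar ATPase texts or also without subunit H and plastid-type texts, and random lists drawn from all measured unigenes or also matched on length.

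The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. They were tested on simulated data. In simulated counts for the WT fiber and FL ovule comparison (53164 measured unigenes), unigenes changed 2-fold, 4-fold, 8-fold and 16-fold were called at least 2-fold higher in 8.0%, 72.0%, 96.0% and 100.0% of cases (50 each). Unchanged unigenes were called in 0.009% of cases. The simulated counts held counting (Poisson) noise only, without variation between plants or library preparations. The 0.009% is therefore not the error rate of the 2-fold differences reported below. On the 41574 annotated unigenes, 2.5% of 200 random lists of 50 unigenes were called apart, and so were 86.0% of 50 lists shifted by 0.5 on the log2 scale.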

Results

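Transcript levels were compared between cotton fiber of the wild-type cultivar Xuzhou142 and ovules of XZ142FLM, a line labelled as having hairless seeds with minimal fiber growth, both at 10 days post anthesis. Cotton fibers are single elongated cells of the seed coat epidermis. The series was designed to find RNA editing sites; editing levels were not analysed here, and the deposited read counts and RPKM values address transcript abundance. There was 1 library per group, with 45.6 M reads for WT fiber and 53.4 M reads for FL ovule. Tissue and genotype differed together between the libraries, so no difference below can be assigned to one of them.

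The libraries differed broadly. Of 63258 measured unigenes, 6659 were at least 2-fold higher in WT fiber and 9697 were at least 2-fold higher in FL ovule. The largest differences were mostly on the fiber side under each scaling tried: 269 unigenes were at least 16-fold higher in WT fiber and 72 were at least 16-fold higher in FL ovule with RPKM as deposited. For all unigenes past 2-fold, the 95% counting interval of the ratio excluded 1, but no replicate checks the difference. The pseudocount, the 2-fold threshold and the read depth made that nearly certain in advance, so the interval is no separate check. Across unigenes, which are not independent replicates, log2(RPKM + 1) in the 2 libraries had a Pearson r of 0.78. The split by direction depended on scaling. WT fiber held 40.7% of the 2-fold differences with RPKM as deposited, 74.3% after rescaling to a common RPKM sum, 60.3% after upper quartile scaling and 18.7% when the 30 most-read unigenes were left out of the totals. The median log2 ratio of all measured unigenes was -0.39 as deposited and 0.23, -0.08 and -0.68 under those 3 scalings, so the gene lists are described relative to matched random lists. The common RPKM sum leans heavily on a few short unigenes, described below.

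**Figure D1:**
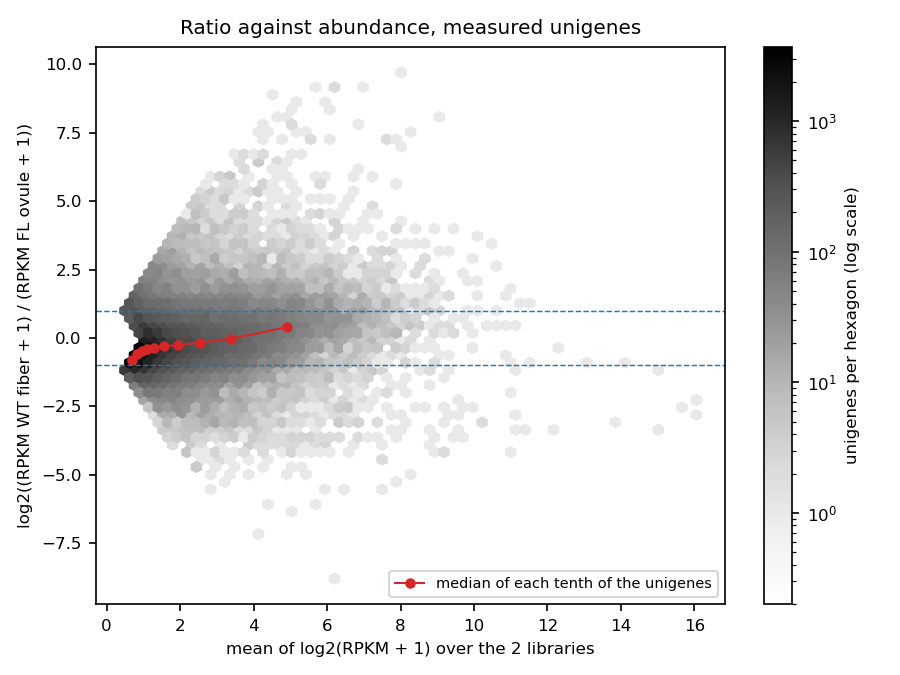
Ratio of WT fiber to FL ovule (y axis, log2 of RPKM + 1) against mean abundance (x axis, mean log2(RPKM + 1)) for 63258 measured unigenes; shading gives the number of unigenes, dashed lines mark 2-fold and red points are medians of 10 groups of equal size. The median was -0.82 in the least abundant 10% of unigenes and 0.39 in the most abundant 10%. The filter of 1 RPKM in at least 1 library holds ratios away from 0 at the lowest abundance.

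The most abundant sequences of both libraries were short unigenes without an informative annotation. By the naming rule these were 6 unigenes of 205 to 498 bases, which together held 4.01% of the reads of WT fiber and 23.0% of the reads of FL ovule. Unigene0037227, annotated as a conserved hypothetical protein, had 25144 RPKM in WT fiber and 183470 RPKM in FL ovule, a 7.30-fold difference (95% counting interval 7.28 to 7.32). Unigene0037226 and Unigene0040794 carried the same annotation text and were 6.19-fold and 2.48-fold higher in FL ovule. Unigene0028362, a hypothetical protein, was 10.9-fold higher in FL ovule. The unannotated Unigene0125152 and Unigene0040795 were 4.98-fold and 1.80-fold higher there. Their sequences are not in the deposited tables, so it could not be checked whether they are ribosomal RNA. If they are, their shares, their folds and the read totals behind RPKM depend on how that RNA was removed from each library. Being short, they weighed more in the RPKM sums than in the read totals. Those sums were 865807 in WT fiber and 1336140 in FL ovule. Unigene0037227, Unigene0125152 and Unigene0037226 alone had 183470, 139443 and 127241 RPKM in FL ovule, against 25144, 27976 and 20547 in WT fiber. Rescaling to a common RPKM sum therefore depended strongly on these unigenes.

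The 10 annotated unigenes with the largest ratios towards WT fiber included an expansin, 2 arabinogalactan proteins and 4 proline-rich proteins. The alpha expansin (Unigene0055966), a protein that loosens the wall of growing cells, had 6967 RPKM in WT fiber and 7.32 RPKM in FL ovule, a 951-fold difference (95% counting interval 871 to 1042). The arabinogalactan protein (Unigene0043142), a cell surface glycoprotein, was 740-fold higher in WT fiber (653 to 842), and fasciclin-like arabinogalactan protein 7 (Unigene0060028) was 656-fold higher (507 to 864). Proline-rich proteins are a class of structural wall proteins. Unigene0028857 was 1100-fold higher (819 to 1514), Unigene0127564 was 827-fold higher (651 to 1068) and Unigene0143923 was 781-fold higher (543 to 1166). Unigene0028858 had 11135 reads in WT fiber and 3 reads in FL ovule, a ratio of 4344 with a counting interval of 1486 to 21066. The others were 3-ketoacyl-CoA synthase 12 (Unigene0030424), a WD40 repeat protein (Unigene0046573) and an auxin binding protein (Unigene0125523), which were 811-fold, 639-fold and 447-fold higher.

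Among the 10 annotated unigenes with the largest ratios towards FL ovule, 3 were annotated as proteases. A protease of the PfpI family (Unigene0034980) had 2.31 RPKM in WT fiber and 1479 RPKM in FL ovule, a 641-fold difference (95% counting interval 482 to 873). An aspartic proteinase (Unigene0049096) was 418-fold higher in FL ovule (303 to 593), and a secretory laccase (Unigene0119947), an enzyme class that oxidizes phenolic compounds, was 564-fold higher on 7 reads in WT fiber (273 to 1403). A berberine family oxidase with an FAD-binding domain (Unigene0037071) was 123-fold higher. Expansin-like B1 (Unigene0048776) was 83.8-fold higher, a pectin methylesterase inhibitor domain protein (Unigene0033153) 46.3-fold higher and a vacuolar-processing enzyme, which is a protease (Unigene0066993), 38.4-fold higher. The remaining 3 of the 10, Unigene0057016, Unigene0128022 and Unigene0009126, had no functional annotation text and were 103-fold, 49.0-fold and 34.3-fold higher.

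**Figure D2:**
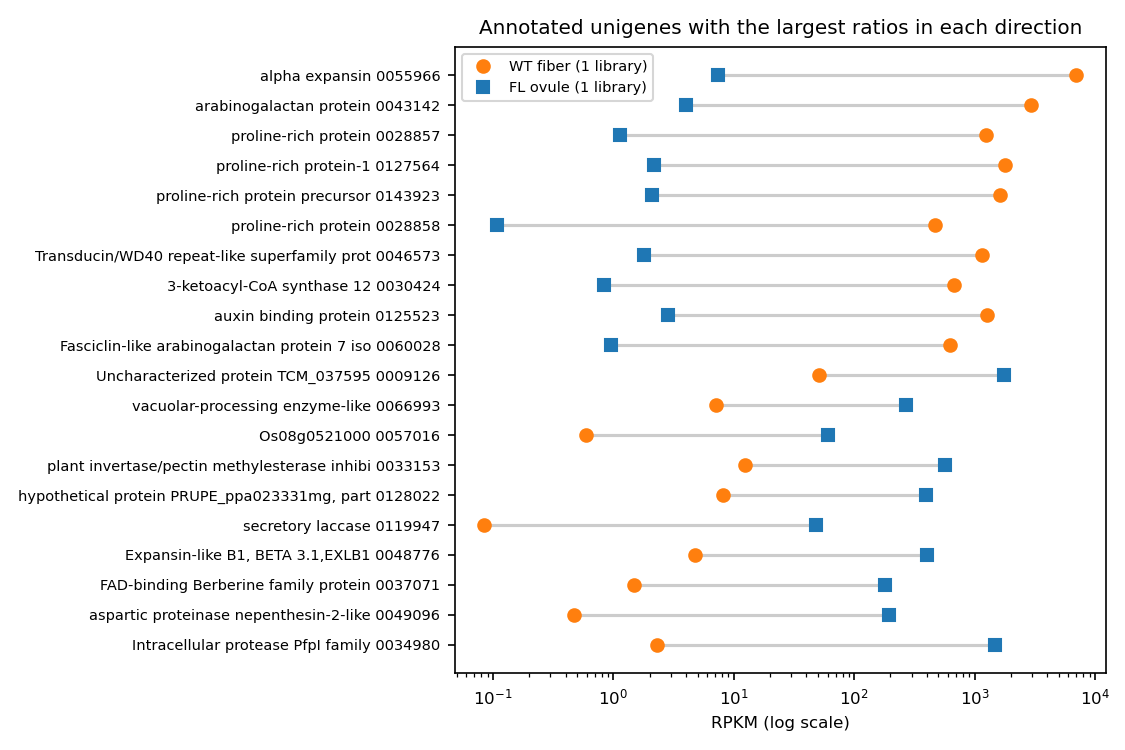
RPKM (x axis, log scale) in WT fiber (circles) and FL ovule (squares) of the 10 annotated unigenes with the largest ratios in each direction, 1 library per group; the unigene number follows each annotation. The alpha expansin stood at 6967 RPKM in WT fiber and 7.32 RPKM in FL ovule, and the PfpI family protease at 2.31 and 1479 RPKM.

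Of the 31 gene lists fixed in advance, 30 had enough members. The medians of 4 lists lay above the range of matched random lists, those of 15 lay below it, and 11 lay within it. About 1.5 lists would fall outside by chance if members were independent, which unigenes of 1 gene are not. The random lists came from annotated unigenes, a choice made after a first result from all measured unigenes had been seen; with all measured unigenes 6 lists lay above and 13 below. Single unigenes do not stand for their annotation: of 77 annotated unigenes named by the rule and past 2-fold, 48 had other measured unigenes with the same text, and 18 of them had one past 2-fold the other way. Some of these texts are broad and need not name 1 gene. The text of the WD40 repeat protein Unigene0046573 was shared by 106 others, 22 of them past 2-fold the other way. Below, the direction of a list is relative to random lists, since the counts past 2-fold shift with scaling.

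**Figure D3:**
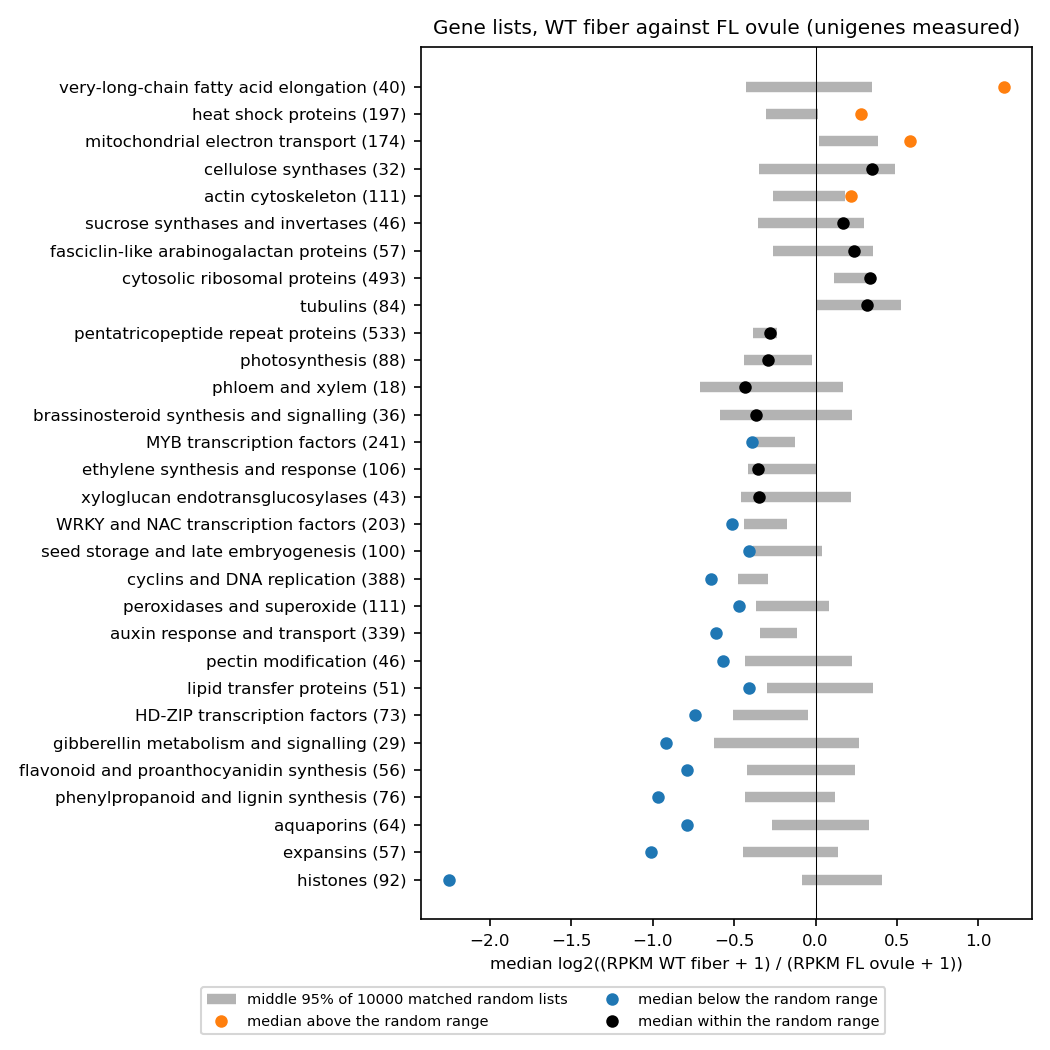
Median log2 ratio of WT fiber to FL ovule (x axis) for 30 gene lists, ordered by distance from the random median, with the number of measured unigenes in brackets; grey bars span the middle 95% of 10000 random lists matched on expression. Fatty acid elongation stood farthest above its bar at 1.16, and histones farthest below at -2.25.

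Members of the wall-related lists differed from each other. Of 57 expansins, 9 were at least 2-fold higher in WT fiber and 29 at least 2-fold higher in FL ovule. Their median log2 ratio of -1.01 lay below the medians of all 10000 random lists, although their summed RPKM was 7.89-fold higher in WT fiber because of Unigene0055966. Of 43 xyloglucan endotransglucosylases, which cut and rejoin wall xyloglucan, 14 were higher in each direction (16 and 7 after rescaling to a common RPKM sum) and the list lay at the 12th percentile, with a median of -0.35 and a mean of 0.26. Their 2 named members, Unigene0120055 and Unigene0050785, were 138-fold and 31.2-fold higher in WT fiber, while the other 3 unigenes with the annotation of Unigene0050785 were at least 2-fold higher in FL ovule. Fasciclin-like and other arabinogalactan proteins were also divided equally, 17 against 17 of 57, with 25 against 8 after that rescaling and 15 against 22 with totals without the 30 most-read unigenes. Their median of 0.23 lay at the 89.7th percentile, but their mean of 0.74 lay at the 99.97th, and the median lay at the 99.8th at 5 RPKM or more and at the 98.97th with 1 unigene per annotation text. Cellulose synthases were at least 2-fold higher in WT fiber in 8 of 32 cases and in FL ovule in 2 (15 and 1 after that rescaling, 7 and 6 with totals without the 30 most-read unigenes), at the 91.0th percentile; Unigene0097193 and cellulose synthase 2-Dt (Unigene0137491) were 9.10-fold and 6.58-fold higher in WT fiber. Pectin-modifying enzymes had a median of -0.57 at the 0.18th percentile and a mean of 0.11 at the 75.4th percentile; with 1 unigene per annotation text the median lay at the 5.92th. Of these 46 unigenes, 8 were higher in WT fiber and 16 in FL ovule (10 and 11 after that rescaling), and 2 pectate lyases, Unigene0080278 and Unigene0080280, were 255-fold and 191-fold higher in WT fiber. The summed RPKM of the pectin list was 2384 in WT fiber against 578 in FL ovule.

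Fatty acid elongation and actin lay above random, on the WT fiber side. Of 40 unigenes in the list for elongation of very-long-chain fatty acids, 22 were at least 2-fold higher in WT fiber and 3 in FL ovule, and the median of 1.16 lay above all 10000 random medians. By its text pattern the list also took in a 2,4-dienoyl-CoA reductase (Unigene0065628), which is not an elongation enzyme. The 3-ketoacyl-CoA synthase Unigene0116972, of the enzyme class that adds carbons to the acyl chain, was 99.6-fold higher in WT fiber. Actin, profilin and actin-depolymerizing factors were higher in WT fiber in 34 of 111 cases and in FL ovule in 13 (30 and 26 with totals without the 30 most-read unigenes), at the 98.8th percentile, which became 90.7 after rescaling to a common RPKM sum, 96.6 with upper quartile scaling and 96.3 with a pseudocount of 5. With those totals the actin median changed sign, from 0.21 to -0.19, and the tubulin median from 0.31 to -0.22. A profilin (Unigene0037908) and actin depolymerizing factor 5 (Unigene0053095) were 401-fold and 59.0-fold higher in WT fiber. Tubulins were higher in WT fiber in 36 of 84 cases and in FL ovule in 16 (35 and 26 with those totals), with 31274 RPKM in sum against 8577. Their median of 0.31 lay at the 59.9th percentile, since random lists of such abundance also leaned to WT fiber, and their mean at the 99.4th; at 5 RPKM or more the median lay above all random medians. The beta-tubulin unigenes Unigene0066687 and Unigene0066683 were 202-fold and 186-fold higher in WT fiber.

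By their medians, transport and sugar lists leaned the other way or neither way. Of 64 aquaporins, which are water channels, 13 were at least 2-fold higher in WT fiber and 26 in FL ovule (17 and 18 after rescaling to a common RPKM sum), and the median of -0.79 lay below all random medians. Aquaporin TIP1;7 (Unigene0056128) was nevertheless 474-fold higher in WT fiber and a PIP2 protein (Unigene0139331) 41.7-fold higher, while 4 of the other 6 unigenes with that PIP2 annotation were at least 2-fold higher in FL ovule. The summed RPKM of aquaporins was 5316 in WT fiber against 3081 in FL ovule, with 53.7% of the former in 1 unigene. Lipid transfer proteins had a median of -0.41 at the 0.37th percentile, with 15 of 51 higher in WT fiber and 23 in FL ovule (18 and 17 after that rescaling). They lay within the random range at 5 RPKM or more (22.1th percentile), with no filter (3.53th) and by the mean (7.28th). Lipid transfer protein 4 (Unigene0044555) was 292-fold higher in WT fiber at 8414 RPKM against 28.8, and Unigene0052447 was 491-fold higher. The summed RPKM of lipid transfer proteins was 12129 in WT fiber against 2657 in FL ovule, with 69.4% of the former in Unigene0044555. Sucrose synthases and invertases lay at the 90.5th percentile, with 10 of 46 higher in WT fiber and 7 in FL ovule (9 and 11 with totals without the 30 most-read unigenes). Sucrose synthase isoform C (Unigene0114882) and a vacuolar invertase (Unigene0082161), both of which cleave sucrose, were 36.7-fold and 21.0-fold higher in WT fiber.

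Histones and cell division genes lay below random, on the FL ovule side. Of 92 histone unigenes, 66 were at least 2-fold higher in FL ovule and 1 in WT fiber. The median of -2.25 lay far below the random range of -0.08 to 0.41, and the summed RPKM was 1438 in WT fiber and 6678 in FL ovule. Histone H3.2 (Unigene0072812) and an H2AX histone (Unigene0038487) were 44.4-fold and 19.9-fold higher in FL ovule. Cyclins and DNA replication genes were higher in FL ovule in 106 of 388 cases and in WT fiber in 42 (50 and 54 after rescaling to a common RPKM sum), and their median of -0.65 lay below all random medians. The 2 members of that list with the largest ratios went the other way. Cyclin p3,2 (Unigene0043383) was 212-fold higher in WT fiber, and SIAMESE (Unigene0015644), an inhibitor of cyclin-dependent kinases, was 96.0-fold higher.

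Respiration and heat shock lists lay above random in WT fiber. The respiratory list, which by its text pattern also took in vacuolar ATPase subunits, was at least 2-fold higher in WT fiber for 47 of 174 members and in FL ovule for 5, with a median of 0.58 at the 99.98th percentile (26 and 9 of 187 with totals without the 30 most-read unigenes). Without the 6 members with vacuolar ATPase texts, a set chosen after the result was seen, the counts were 45 and 4 of 168, with a median of 0.57 at the same percentile. Unigenes tagged as mitochondrial, another such set, lay within the random range at the 36.4th percentile. The 2 named members of the respiratory list were ATPase subunits. An H subunit (Unigene0025135) was 7.34-fold higher in WT fiber, and a unigene of 201 bases related to the vacuolar ATPase (Unigene0024629) was 18.5-fold higher in FL ovule. Heat shock proteins, fixed as a marker of stress or RNA handling, were higher in WT fiber in 42 of 197 cases and in FL ovule in 14, and the median of 0.28 lay above all random medians. With totals without the 30 most-read unigenes it was -0.06, with 33 and 28 unigenes past 2-fold, and at 5 RPKM or more it lay at the 97.1th percentile, within the range. Heat shock protein 70B (Unigene0105439) and a heat shock protein 83 (Unigene0058879) were 71.8-fold and 23.1-fold higher in WT fiber. Cytosolic ribosomal proteins were higher in WT fiber in 100 of 493 cases and in FL ovule in 14, at the 97.0th percentile, just within the random range. With the same totals the counts were 52 and 49 and the median of 0.34 became -0.01, but random lists shifted too and the percentile was 99.3. It lay above the random range under 8 alternatives in all. Ribosomal protein L24-1 was 170-fold higher in WT fiber for Unigene0016979 (78.0 to 466, on 6 reads in FL ovule) and 46.9-fold for Unigene0016980.

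Among hormone lists, auxin and gibberellin genes were lower in WT fiber than random lists. Of 339 auxin-related unigenes, 94 were at least 2-fold higher in FL ovule and 45 in WT fiber (49 and 53 after rescaling to a common RPKM sum), with a median of -0.61 below all random medians. The auxin-induced protein 6B unigene (Unigene0052561) was 25.6-fold higher in WT fiber. The summed RPKM of the auxin list was 3970 in WT fiber against 2849 in FL ovule. Of 29 gibberellin unigenes, 13 were higher in FL ovule and 5 in WT fiber (7 and 5 after that rescaling), with a median of -0.92, also below all random medians. Gibberellin 20-oxidase 1 (Unigene0073254), an enzyme of gibberellin synthesis, was 5.92-fold higher in FL ovule. Another unigene with the same annotation (Unigene0073251), named after its values were seen, was 2.15-fold higher in WT fiber, at 105 RPKM against 48.8. A gibberellin-regulated protein (Unigene0011810) was 231-fold higher in WT fiber on 7 reads in FL ovule. Ethylene genes lay at the 8.60th percentile, with 6 of 106 higher in WT fiber and 18 in FL ovule (11 and 5 after rescaling to a common RPKM sum). They lay below the range at 5 RPKM or more (2.43), by the mean (1.41), with no filter (1.67) and with a pseudocount of 5 (0.74). Their named members were an ethylene-responsive element binding protein (Unigene0025434), 29.8-fold higher in WT fiber, and the AP2 factor AIL6 (Unigene0139337), 18.6-fold higher in FL ovule. Brassinosteroid genes lay at the 27.3th percentile, with a median of -0.36, a mean of 0.01 and 6 of 36 in each direction (9 and 0 after that rescaling, 6 and 12 with totals without the 30 most-read unigenes). A steroid 5-alpha-reductase (Unigene0068109), an enzyme of brassinosteroid synthesis, and a BRI1-associated receptor kinase (Unigene0083981) were 7.43-fold and 7.82-fold higher in WT fiber.

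The 3 lists of transcription factors lay below random, MYB and WRKY and NAC not under all alternatives. HD-ZIP factors had a median of -0.74, below all random medians, with 7 of 73 higher in WT fiber and 21 in FL ovule (12 and 6 after rescaling to a common RPKM sum). Unigene0039009 and Unigene0089152, both annotated as PROTODERMAL FACTOR 2, a factor of the outer cell layer, were 22.0-fold and 9.56-fold higher in FL ovule. MYB factors, a family that includes trichome regulators, had a median of -0.39 at the 1.61th percentile, with 26 of 241 higher in WT fiber and 61 in FL ovule (39 and 35 after that rescaling); against random lists from all measured unigenes they lay at the 14.0th. Myb domain protein 60 (Unigene0053935) was 199-fold higher in WT fiber, and Myb domain protein 52 (Unigene0068215) was 33.2-fold higher in FL ovule. WRKY and NAC factors had a median of -0.51 at the 0.08th percentile, with 18 of 203 higher in WT fiber and 47 in FL ovule (30 and 25 after that rescaling). At 5 RPKM or more they lay at the 4.38th percentile, and with 1 unigene per annotation text at the 7.91th, within the range. NAC factor 3 (Unigene0075089) was 25.8-fold higher in WT fiber. NAC domain protein 38 (Unigene0131117) had 2 reads in WT fiber and 679 in FL ovule, a ratio of 290 with a counting interval of 80.0 to 2400.

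Phenylpropanoid and flavonoid lists lay below random, on the FL ovule side. Of 76 phenylpropanoid and lignin unigenes, 38 were at least 2-fold higher in FL ovule and 16 in WT fiber, with a median of -0.97 below all random medians; laccase 11 (Unigene0066066) was 34.3-fold higher in FL ovule. Flavonoid and proanthocyanidin unigenes, fixed as a seed coat marker, were higher in FL ovule in 24 of 56 cases and in WT fiber in 11 (15 and 15 after rescaling to a common RPKM sum). Their median of -0.79 lay below all random medians, and their summed RPKM was 3.52-fold higher in FL ovule. For chalcone synthase, which opens the flavonoid pathway, Unigene0022155 was 27.8-fold higher in FL ovule and Unigene0043038 was 24.2-fold higher in WT fiber. The other 7 unigenes with the annotation of Unigene0043038, among them Unigene0022155, were all at least 2-fold higher in FL ovule. The most abundant of them (Unigene0082097), named after its values were seen, had 276 RPKM in WT fiber and 1886 RPKM in FL ovule. Peroxidases and other reactive oxygen enzymes had a median of -0.47 at the 0.04th percentile, with 17 of 111 higher in WT fiber and 38 in FL ovule (29 and 22 after that rescaling). At 5 RPKM or more they lay at the 40.1th percentile, within the range. The 2 named peroxidases, Unigene0122711 and the ascorbate peroxidase Unigene0077803, were 36.6-fold and 552-fold higher in WT fiber, the latter on 4 reads in FL ovule (215 to 2029). The other unigene with the annotation of Unigene0122711 (Unigene0054407), named after its values were seen, was 12.3-fold higher in FL ovule, at 2864 RPKM against 234.

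The other tissue markers were less clear. Seed storage and late embryogenesis unigenes, fixed as markers of embryo and endosperm, lay at the 1.27th percentile, with 21 of 100 higher in WT fiber and 37 in FL ovule (27 and 25 after rescaling to a common RPKM sum, at the 2.51th percentile). Their text pattern also took in texts that name a joint family of inhibitors, lipid transfer and seed storage proteins, which do not single out storage proteins. They lay within the range under 6 alternatives, up to the 10.4th percentile with a pseudocount of 0.1. A late embryogenesis abundant protein (Unigene0123729) was 262-fold higher in WT fiber, and a protein of the seed storage and lipid transfer family (Unigene0025831) was 25.6-fold higher in FL ovule. Photosynthesis genes lay at the 31.4th percentile, with 9 of 88 higher in WT fiber and 17 in FL ovule (17 and 9 after that rescaling). They lay at the 1.01th percentile at 5 RPKM or more and at the 99.96th with no filter, on opposite sides. Of the pathway labels in the tables, examined after the data were seen, photosynthesis antenna proteins lay below all random medians (23 unigenes, median -0.91). A Rubisco family protein (Unigene0051857) and a chlorophyll binding protein (Unigene0074073) were 12.9-fold and 28.9-fold higher in FL ovule. The summed RPKM of the photosynthesis list went the other way, 1265 in WT fiber against 839 in FL ovule, with 48.7% of the WT fiber sum in 1 unigene. Phloem and xylem markers lay at the 30.2th percentile, with 1 of 18 higher in WT fiber and 4 in FL ovule. Xylem cysteine peptidase 1 (Unigene0056010) was 7.37-fold higher in FL ovule, and a phloem protein 2-like unigene (Unigene0126402) was 6.24-fold higher in WT fiber.

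Pentatricopeptide repeat (PPR) proteins were compared as nuclear factors of organelle RNA. This family binds organelle RNA and includes editing factors. Of 533 PPR unigenes, 14 were at least 2-fold higher in WT fiber and 26 in FL ovule (40 and 6 after rescaling to a common RPKM sum, 8 and 100 with totals without the 30 most-read unigenes). The median of -0.28 lay at the 77.9th percentile, at the 99.8th against random lists from all measured unigenes and at the 97.9th with totals without the 30 most-read unigenes. The PPR unigene Unigene0067075 was 12.8-fold higher in WT fiber, and Unigene0072814 was 15.4-fold higher in FL ovule; the number of Unigene0072814 stands among those of histone unigenes. The list of named organelle editing factors had 2 measured members, too few for a comparison. One of them, multiple organellar RNA editing factor 1 (Unigene0083524), named after its values were seen, had 26.2 RPKM in WT fiber and 21.2 RPKM in FL ovule.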

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

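Totals without the 30 most-read unigenes, 1 unigene per annotation text, thinned reads, the respiratory list without members of other complexes, length-matched random lists and random lists from all measured unigenes were chosen after the data were seen. Random lists from all measured unigenes, the first choice before annotated ones were used, put 6 lists above and 13 below the random range, against 4 and 15. The groups hold 1 library each, so no replicate could be left out. The 6659 unigenes higher in WT fiber became 1771 at a 4-fold threshold, 4307 at 5 RPKM or more, 3780 with 1 unigene per annotation text, 2892 with a pseudocount of 5 and 11478 after rescaling to a common sum. The 9697 higher in FL ovule became 1387, 3548, 6071, 1832 and 3960 under those settings, 23140 with a pseudocount of 0.1, 24452 with totals without the 30 most-read unigenes and 6062 with upper quartile scaling. The thresholds and filters count fewer unigenes by construction; the cause of the other moves was not tested beyond the change of scale. Recomputed log2 ratios of named unigenes shifted by no more than the reach of their counting interval in 413 cases. They shifted by more in 282. The 413 include 79 values at 5 RPKM or more, 79 with no filter and 63 without the 100 most abundant unigenes. Those 3 settings leave each ratio as it was, so these values could not move. Of the lists called apart, 2 of 4 on the WT fiber side and 9 of 15 on the FL ovule side stayed on their side of the threshold under all settings. Percentiles that crossed it were, for lists otherwise below random: MYB 14.0 (all measured unigenes); WRKY and NAC 4.38 (5 RPKM) and 7.91 (1 per text); lipid transfer 22.1 (5 RPKM), 7.28 (mean) and 3.53 (no filter); pectin 5.92 (1 per text) and, in the other direction, 75.4 (mean); peroxidases 40.1 (5 RPKM). Seed storage gave 6.55 (no filter), 10.4 (pseudocount 0.1), 2.63 (length), 5.31 (all measured unigenes), 2.51 (common sum) and 2.73 (upper quartile). For lists otherwise above random, actin gave 96.3 (pseudocount 5), 90.7 (common sum) and 96.6 (upper quartile), and heat shock 97.1 (5 RPKM). Lists within the range moved out of it as follows. Ribosomal proteins gave 97.6 (above 0 in both libraries), 98.3 (median scaling), 99.9 (no filter), 99.4 (pseudocount 5), 99.7 (all measured unigenes), 97.8 (common sum), 99.3 (totals without 30) and 98.2 (upper quartile). Ethylene gave 2.43 (5 RPKM), 1.41 (mean), 1.67 (no filter) and 0.74 (pseudocount 5). Arabinogalactan proteins gave 99.8 (5 RPKM), 99.97 (mean) and 98.97 (1 per text), tubulins 100 (5 RPKM) and 99.4 (mean). PPR proteins gave 99.8 (all measured unigenes) and 97.9 (totals without 30), photosynthesis 1.01 (5 RPKM), 99.96 (no filter) and 98.2 (totals without 30). The cause of these crossings was not tested. The respiratory list stayed above random without vacuolar ATPase texts (99.98) and also without subunit H and plastid-type texts (median 0.55 for 154 unigenes, above all random medians). Thinning FL ovule to the WT fiber total, which leaves the expected RPKM as it was, gave 6667 unigenes higher in WT fiber and 9866 higher in FL ovule, close to the counts at full depth. That simulated 2-fold changes were called in only 8.0% of cases follows from the pseudocount and the 2-fold threshold, not from depth alone.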

Other observations

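The gene groups, pathways and unigenes below were chosen after their results had been seen at least in part. So were the tests of scaling, depth, dividing cells, retroelements and the PPR unigene. The test of unigene length was also chosen after the data were seen, but its prediction was written before its result. Lists for vesicle transport and proton pumping lay above random, on the WT fiber side, with RPKM as deposited; other scalings were not run on the added lists. Of 38 unigenes of the vacuolar proton pump, 20 were at least 2-fold higher in WT fiber and 1 in FL ovule, with a median log2 ratio of 1.06 above all 10000 matched random medians; subunit C2 (Unigene0076873) had 438 RPKM in WT fiber and 60.8 RPKM in FL ovule. Their summed RPKM went the other way, 2679 in WT fiber against 3004 in FL ovule, since the 1 unigene higher in FL ovule (Unigene0024629, 201 bases) held 75.6% of the FL ovule sum. Of 347 unigenes for SNAREs, vesicle coats and the exocyst, 87 were higher in WT fiber and 13 in FL ovule, with a median of 0.48, again above all random medians. Syntaxin of plants 121 (Unigene0066420) had 136 RPKM in WT fiber and 7.61 RPKM in FL ovule, while syntaxin of plants 111 (Unigene0059274) had 2.07 RPKM in WT fiber and 30.4 RPKM in FL ovule. Of 75 unigenes whose text names fiber, 33 were higher in WT fiber and 2 in FL ovule; such names are tied to the tissue, so this list is not independent of it. Fiber protein Fb28 (Unigene0122856) had 3108 RPKM in WT fiber and 24.3 RPKM in FL ovule.

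Pathway labels in the tables covered 205 pathways with at least 20 measured unigenes, of which 39 lay above and 30 below the random range, against about 10.2 outside by chance if pathways were independent, which they are not, since they share unigenes. The pathway for protein processing in the endoplasmic reticulum had 104 of 485 unigenes higher in WT fiber and 15 in FL ovule, and N-glycan biosynthesis had 16 and 2 of 96. Flavonoid biosynthesis had 31 of 45 unigenes higher in FL ovule and 4 in WT fiber, and zeatin biosynthesis had 10 and 2 of 22. The spliceosome had 26 and 17 of 352, with a median of -0.39 against a random median of -0.006. Photosynthesis antenna proteins lay below all random medians, with 9 of 23 unigenes higher in FL ovule and 1 in WT fiber, while the photosynthesis pathway had 14 and 13 of 72. Cytokinin unigenes by text were higher in FL ovule in 11 of 25 cases and in WT fiber in 1, and carotenoid and abscisic acid unigenes lay within the random range with a median of -0.26. Unigenes tagged as mitochondrial lay within the random range at a median of 0.26 and held 3.65% of the reads of WT fiber and 3.25% of those of FL ovule. Within this group ATPase subunit 4 (Unigene0088562) had 3294 RPKM in WT fiber and 1033 RPKM in FL ovule, while ATP synthase F1 subunit 1 (Unigene0097138) had 1552 and 3194 RPKM. The labels do not say whether the oligo-dT or the ribosomal-RNA-depleted part was counted, and values of mitochondrial transcripts may depend on that.

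The first pattern is the low level of histones in WT fiber. Composition or scaling of the libraries does not account for the whole of it, since the highest histone median under the rescalings tried was -1.68. Short unigenes do not account for it either: the lowest of 10000 random medians matched on expression and length was -0.35, against -2.25 for histones. A candidate explanation is fewer dividing cells in the fiber library, and mitotic and replication unigenes had a median of -0.73, below the random range of -0.51 to 0.17. That list shares members with the cyclin and DNA replication list, which had already been seen below random, so it is not an independent test. Cyclin-dependent kinase B2,2 (Unigene0052296) had 7.77 RPKM in WT fiber and 105 RPKM in FL ovule, but tissue and genotype remain confounded.

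The second pattern is that unigenes of low abundance leaned to FL ovule. The median log2 ratio went from -0.82 in the lowest 10% to 0.39 in the highest 10%. The filter sets part of the lowest value: at the lowest mean, 1 RPKM in 1 library leaves less in the other, which holds ratios away from 0. The sign there partly reflects which library had more unigenes at 1 RPKM, 57220 in FL ovule against 39945 in WT fiber. Without the filter the median of all unigenes was -0.24, and at 5 RPKM or more 0.06. A single scaling factor would move all unigenes towards the same library, while the medians of the lowest and highest 10% had opposite signs. Their 95% intervals were -0.83 to -0.82 and 0.36 to 0.42 over 1000 resamples of unigenes, which are not independent. That does not settle the question, since a factor also changes which unigenes pass the filter. Rescaling to a common RPKM sum left 54584 measured unigenes against 63258. The medians by abundance were not recomputed under other scalings. Left uncorrected, the difference in read totals would shift log2 ratios by -0.23, and the lowest 10% lay further down. That comparison cannot test depth, since RPKM already divides by the totals. Thinning FL ovule to the WT fiber total gave 6667 unigenes higher in WT fiber and 9866 in FL ovule, close to 6659 and 9697 at full depth. The medians by abundance were not recomputed after thinning. Genomic DNA or unspliced RNA in the FL ovule library may contribute: retroelement unigenes had a median of -0.65, below the range of -0.52 to -0.40 of random lists of similar abundance, yet annotated unigenes of the less abundant 50% also had -0.46. A larger number of cell types in an ovule than in fiber stays open and was not tested.

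The third pattern is Unigene0072814, annotated as the PPR protein At4g32430, whose log2 ratio of -3.75 was the lowest of 533 PPR unigenes, with the next at -1.85. Its number lies among 6 histone unigenes with ratios from -4.70 to -1.85. Consecutive numbers carried the same annotation text in 41.2% of annotated pairs, against 0.028% of random pairs, so neighbouring numbers are often related sequences. The unigene may therefore carry histone reads, through a joined sequence for example. The 1 other measured unigene with the same annotation text had a ratio not below -1.85. A true difference of this PPR gene between the samples stays open, since the sequence itself was not examined.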
